A study of Taxus x media with 6 samples.

How the data were processed

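RNA was measured by sequencing of poly(A)-selected RNA from twigs of Taxus × media, an evergreen hybrid yew with separate female and male trees. Per the labels' protocols, the twigs came from independent trees, 3 female and 3 male, the trees grew under one set of controlled light and humidity conditions, mRNA was captured on oligo(dT) beads and fragmented, and the libraries were read on an Illumina HiSeq 4000. Each library was taken as one tree and one replicate of its sex.

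The authors deposited one table per library with one value per gene. The unit is not named in the sources used here and was read from the deposited values as TPM (transcript abundance scaled to a fixed total per library): the values are not whole numbers, low values share no common step, and each library sums to between 997065 and 998035. Genes carry identifiers in the style of the Trinity de novo assembler, per the file headers and rows, in which genes of one component (the same DN and c numbers) come from one connected part of the assembly and can be gene copies, sequence versions or fragments. The tables list 43846 genes in 24671 components, of which 15618 have 1 listed gene. In every listed gene the highest of the 6 values is at least 2.01 TPM, so weaker genes were left out before deposit. Read trimming, assembly settings, quantifier and any annotation are not given in the sources used here. TPM keeps no read depth, so the depth per library is unknown and no counting interval can be given. An exact 0 is reported as "listed at 0", since the number of reads behind it is not known. TPM is also relative: a rise of abundant genes lowers all others in the same library.

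The sources used here pair no identifier with a gene name. The gene lists fixed before the data were examined could therefore not be matched, and the test planned for them was not made. The rule for named genes then allowed only the 2 genes with the largest fold change in each direction, among genes with an adjusted p under 0.05, a mean of at least 1 TPM in the higher sex and no overlap between the sexes. No genome position or annotation is given for any gene.

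From the deposited TPM, values were transformed as log2(TPM + 1). Genes with at least 1 TPM in 3 or more libraries were tested, which kept 41430 genes and left out 2416. Female and male trees were compared in limma 3.58.1 (R 4.3.3) with an intensity trend, sex as the only term, two-sided, and Benjamini-Hochberg adjustment over all tested genes at 0.05. Log2 fold changes are female minus male on the log2(TPM + 1) scale, which understates the change of low genes. Standard errors are limma's moderated ones. Genes listed at 0 in all 3 libraries of one sex and at 1 TPM or more in all 3 of the other were counted without a test. Library measures were compared by exact two-sided permutation tests, which with 3 against 3 cannot give a p below 0.1. No sequencing batch or date is in the labels. The numbers 1 to 3 count trees within a sex, so the model had no replicate block.

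The fit was tested on simulated data: values for the 41430 genes were drawn from the real means and within-sex spreads. Each gene and library was drawn independently as normal noise, once per setting. Deviations that many genes of a library share are absent from such draws, so the shares below do not show error control in the real data. Recovery was not simulated for changed genes under about 5 TPM. With no changed gene it made 0 calls. With 200 changed genes of about 5 TPM or more it recovered 42.0% of 2-fold, 76.0% of 4-fold, 92.0% of 8-fold and 88.0% of 16-fold changes, and 6.3% of its calls were false. With 4000 changed genes, nearer the number called in the data, it recovered 62.2%, 84.4%, 93.3% and 97.4% of these changes, and 5.5% of its calls were false.

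The alternatives fixed beforehand were quantile normalization, TMM-type scaling of the TPM (an unweighted trimmed mean of log ratios, with 30% of ratios and 5% of levels trimmed at each end), no filter, a filter of 5 TPM in 3 libraries, pseudocounts of 0.1 and 0.01, limma without the trend, limma with array weights, a test against a 2-fold change (treat), the replicate number as a block, each library left out in turn with the same genes tested, and floors of 0.5 and 2 TPM for genes of one sex. Sums over Trinity components, and removal of the genes above 0 in female tree 2 alone, were added after the data were seen, as was leaving out each library for the library measures and correlations.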

Results

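Gene expression was measured in twigs of 6 Taxus × media trees, 3 female and 3 male. Each library gave TPM values for the same 43846 assembled genes, of which 34152 were above 0 in all 6 libraries. Between 38652 genes (female tree 1) and 41505 genes (female tree 2) were above 0 in a library, and the median gene ranged from 3.23 TPM in female tree 1 to 5.25 TPM in male tree 2. The 10 most abundant genes took 11.1% ± 1.14 of the TPM in female trees and 10.3% ± 0.827 in male trees (mean ± SD, n = 3 per sex). That difference, with an exact permutation p of 0.3, was within the spread between trees. The number of genes above 0 was 40261 ± 1461 in female and 40548 ± 818 in male trees (SD, n = 3), with an exact permutation p of 0.8. For the 100 most abundant genes the shares were 29.4% ± 2.09 and 29.2% ± 2.16 (SD, n = 3), with an exact permutation p of 1. None of the 6 library measures compared in this way, which also included the TPM total (exact permutation p = 0.4), had a Benjamini-Hochberg adjusted p below 0.9. The depth behind each value is unknown, because TPM does not keep it.

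The libraries separated by sex. Over the 41430 tested genes, the correlation of log2(TPM + 1) averaged 0.886 ± 0.0135 (SD over 3 pairs) among female trees, 0.898 ± 0.0153 among male trees and 0.792 ± 0.00906 over the 9 pairs of a female and a male tree. The lowest correlation within a sex was 0.872, between female trees 1 and 2, and the highest across sexes was 0.810, between female tree 1 and male tree 1. The pairs share libraries, so these SDs describe the pairs and are not errors of independent values. The first principal component, with 47.9% of the variance, placed the 3 female trees on one side and the 3 male trees on the other. The second, with 19.97%, set female tree 1 and male tree 1 apart from the other 4 libraries. These were the library of each sex with the fewest genes above 0 (38652 and 39636). The median within-sex SD of a gene was 0.360 log2 units in female and 0.312 in male trees. Over the pairs left when 1 tree is taken out, which give lower SDs than 3 trees, it was 0.267, 0.254 and 0.298 without female trees 1, 2 and 3 and 0.203, 0.239 and 0.252 without male trees 1, 2 and 3.

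**Figure D1:**
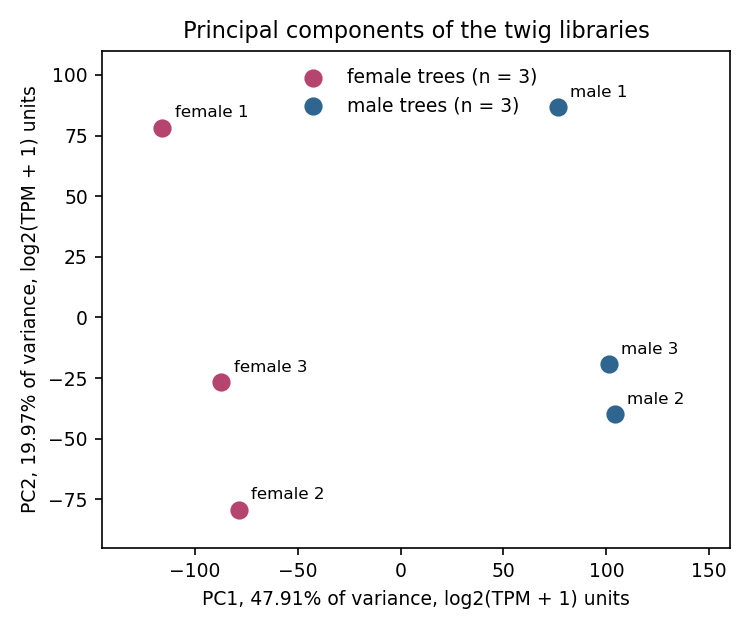
The first 2 principal components of log2(TPM + 1) over the tested genes, one point per tree, female in red and male in blue (n = 3 each), with the axes in log2(TPM + 1) units. PC1 (47.9% of the variance) separates the sexes, and PC2 (19.97%) sets female tree 1 and male tree 1 above the others.

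Female tree 2 carried a set of genes that no other library had. In that library 1215 genes had at least 1 TPM and were listed at 0 in all of the other 5, against 3 to 12 such genes in each of the other libraries. They made up 2.44% of its TPM, with a median of 18.6 TPM and a highest value of 91.7 TPM. None of them entered the test between the sexes, which asked for 1 TPM in 3 libraries. Counts between the sexes are therefore also given without this tree.

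The comparison of female with male trees asked which genes differ between the sexes. The title of the series names a difference between the sexes in taxoids, the class of yew diterpenoids that includes the anticancer drug paclitaxel, and a regulatory complex of MYB and bHLH proteins, which are families of plant transcription factors. Genes of the taxoid pathway and of these families were not analysed here by name. Of the 41430 tested genes, 4825 (11.6%) differed between the sexes in limma at an adjusted p under 0.05. Among them 1951 were higher in female and 2874 higher in male trees. In each of the 4825 genes all 3 libraries of one sex lay above all 3 of the other. With 3 trees per sex, genes that overlap could not pass this threshold, so the lack of overlap is no further result. Among all tested genes, female libraries lay wholly above male ones in 5240 (12.6%) and wholly below in 7639 (18.4%), where chance gives 5% each way. The labels do not give the parentage of the trees. A difference between the sexes can therefore not be told from one of parentage shared within a sex.

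The median fold among called genes was 3.33 for those higher in female trees and 3.42 for those higher in male trees, on the log2(TPM + 1) scale. At least 2-fold differences were called in 1508 genes higher in female and 2417 higher in male trees. These counts were 1299 and 2011 without female tree 2, 997 and 1499 without male tree 2, and 929 and 1437 without male tree 3. They were 1717 and 2239 under TMM-type scaling and 1920 and 2036 under quantile normalization. At least 8-fold differences were called in 206 and 298 genes, and at least 32-fold differences in 11 and 16. Tested directly against a 2-fold change with limma's treat, 374 genes were higher in female and 530 higher in male trees. The genes higher in female trees held 7.89% ± 0.291 of the TPM in female and 3.61% ± 0.0396 in male trees (SD, n = 3). For the genes higher in male trees these shares were 2.89% ± 0.0640 in female and 7.29% ± 0.279 in male trees. Both sets were chosen on these libraries, so the shares describe their size and are no further test.

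**Figure D2:**
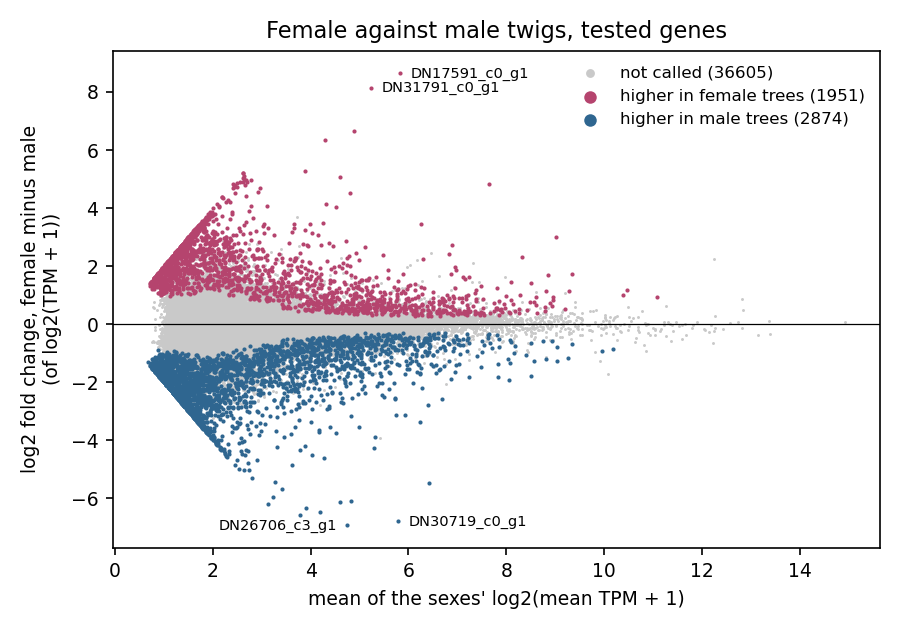
Log2 fold change (female minus male, of log2(TPM + 1)) against expression level for the 41430 tested genes, one point per gene, with genes higher in female trees in red (1951), higher in male trees in blue (2874) and the rest in grey. Called genes occur over most of the range of levels, and the straight edges at low level are genes at or near 0 in one sex.

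The median tested gene was lower in female trees by 0.11 on the log2 scale, and TMM-type scaling moved this median up by 0.103 and quantile normalization by 0.136. The share of called genes that were higher in male trees was 59.6% as deposited, 53.5% after TMM-type scaling and 50.6% after quantile normalization. Without female tree 2 the test called 4065 genes (1705 higher in female, 2360 higher in male), 3452 of them among the 4825. The count of all calls was 2792 without male tree 2 and 2613 without male tree 3. Genes higher in female trees numbered 1263, 1144 and 1054 without male trees 1, 2 and 3 in turn. Genes higher in male trees numbered 1909 without female tree 1, 1908 without female tree 3, 1648 without male tree 2 and 1559 without male tree 3. In all 6 such fits 2149 genes (868 higher in female, 1281 higher in male) were called in the same direction.

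The gene with the largest rise in female trees was TRINITY_DN17591_c0_g1. It stood at 1036 ± 256 TPM in female and 2.13 ± 2.13 TPM in male trees (SD, n = 3), a log2 fold change of 8.64 ± 0.587 (SE; limma adjusted p = 0.00134). TRINITY_DN31791_c0_g1 followed with 621 ± 270 TPM in female and 1.28 ± 1.11 TPM in male trees (SD, n = 3), a log2 fold change of 8.14 ± 0.534 (SE; limma adjusted p = 0.00118). Both were listed at 0 in male tree 1. Of the 2 genes with the largest folds towards male trees, TRINITY_DN26706_c3_g1 stood at 293 ± 53.9 TPM in male and 1.47 ± 0.805 TPM in female trees (SD, n = 3), a log2 fold change of -6.93 ± 0.254 (SE; limma adjusted p = 0.000397). TRINITY_DN30719_c0_g1 stood at 480 ± 102 TPM in male and 5.29 ± 4.67 TPM in female trees (SD, n = 3), a log2 fold change of -6.79 ± 0.848 (SE; limma adjusted p = 0.005). It was listed at 0 in female tree 1, and with a pseudocount of 0.01 its limma adjusted p was 0.109. The order of these 2 genes turned with pseudocounts of 0.1 and 0.01 and without female tree 2 or 3. TRINITY_DN26706_c3_g1 has 1 other listed gene in its component, so its reads could have been divided with that gene, and the other 3 have none.

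**Figure D3:**
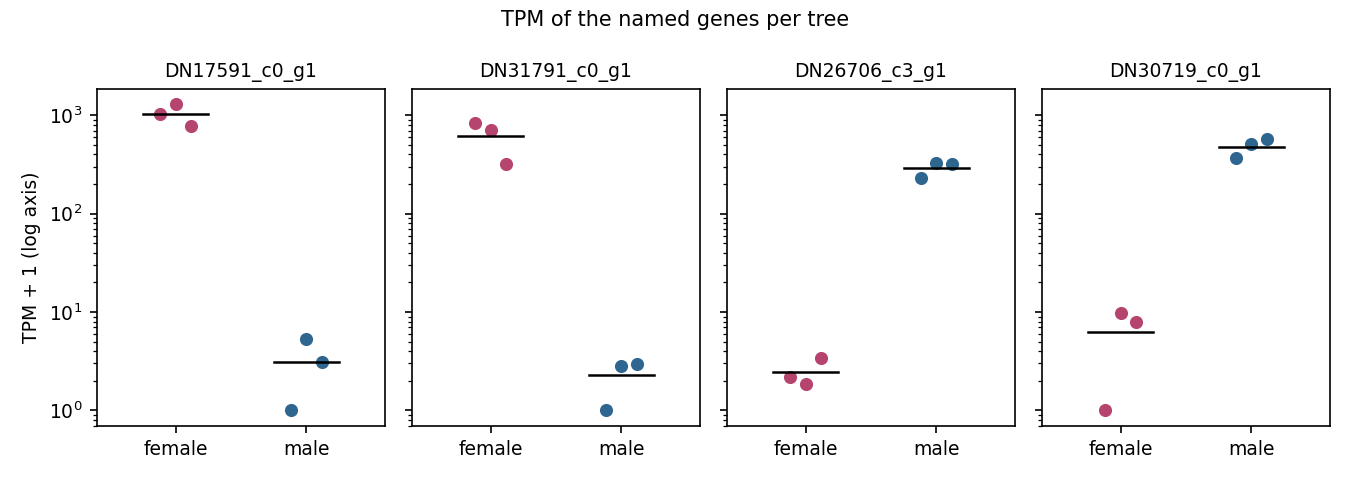
TPM + 1 on a log axis for the 2 genes with the largest fold towards each sex, one point per tree (n = 3 per sex), with a line at the mean TPM + 1. In each gene the 3 trees of one sex lie far above the 3 of the other, as for TRINITY_DN17591_c0_g1 with 1036 TPM in female and 2.13 TPM in male trees on average.

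Genes present in one sex and listed at 0 in the other were counted next. In all 3 female libraries 420 genes had at least 1 TPM while all 3 male libraries were listed at 0, and 645 genes showed the reverse. Their median levels were close, at 5.45 TPM in female and 5.47 TPM in male trees, and 49 and 88 of them averaged 10 TPM or more. They made up 0.272% of the TPM of female trees and 0.410% of that of male trees. Each other choice of 3 libraries, mixing the sexes, gave between 3 and 33 genes. Without female tree 2 the counts of genes of one sex were 452 for the remaining female libraries and 878 for the male ones. They were closer without male tree 2 (615 and 661) and without male tree 3 (541 and 664). Over all left-out libraries they ranged from 448 to 615 and from 661 to 943. Leaving out a library drops a condition, so both counts can only rise. Leaving out a male tree relaxes the rule of 0 in all male libraries and so lifts the female count. Leaving out a female tree does the reverse. These counts therefore do not test the difference between 420 and 645. With a floor of 0.5 TPM they were 457 and 687, and with 2 TPM 301 and 460. After summing TPM over Trinity components, 145 components were present in female and listed at 0 in male libraries and 224 the reverse. Another listed gene was in the component for 290 of the 420 genes and 445 of the 645 genes. In 228 of the 290 and 331 of the 445, the other genes of the component summed to at least 1 TPM in every library of the opposite sex.

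**Figure D4:**
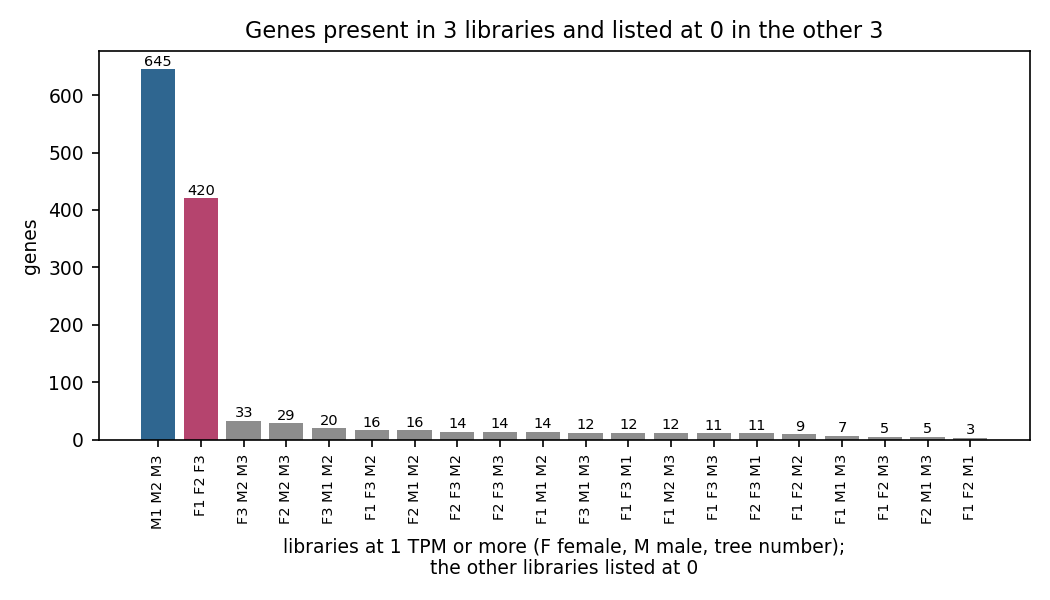
Number of genes at 1 TPM or more in 3 libraries and listed at 0 in the other 3, for each of the possible choices of libraries, with the male trees in blue, the female trees in red and mixed choices in grey. The choices that match the sexes give 645 and 420 genes, and the mixed ones 3 to 33.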

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

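No alternative reversed a called gene: in every limma fit on the same genes, none of the 4825 that was tested there changed direction. The sexes do not overlap in any of the 4825, so most of these fits could not have turned a direction. Only the scalings and the removal of genes with rescaling could have, so the other fits do not test direction. Quantile normalization, TMM-type scaling, no filter, both pseudocounts, limma without the trend, limma with array weights and removal of the genes private to female tree 2 kept the counts of all calls, of calls by direction and of 2-fold calls within 1.5 times. At 100 TPM or more, calls moved further under TMM-type scaling (84 to 47 higher in male) and without the trend (131 to 55 higher in female, 84 to 44 higher in male). With the replicate number as a replicate block 3694 genes were called, 3382 of them among the 4825. Deviations of same-numbered trees correlated at 0.175, 0.071 and -0.042 for numbers 1, 2 and 3. Those of differently numbered trees correlated at -0.149 to 0.105. The value for number 1 was the highest, and the second principal component also set these trees apart. Whether the numbers mark a factor shared by trees is not settled by these values. A filter of 5 TPM in 3 libraries, which tested 20587 genes, called 2787 (1185 higher in female, 1602 higher in male; 688 and 1106 by at least 2-fold). The test against a 2-fold change called 904 (374 and 530). Sums over components, which tested 23303 units, called 2394 (952 and 1442; 618 and 1053 by at least 2-fold), and left 145 components of female and 224 of male trees listed at 0 in the other sex. Leaving out each library gave 2613 to 4065 calls, 1054 to 1705 higher in female, 1559 to 2360 higher in male, and 929 to 1299 and 1437 to 2069 by at least 2-fold. It moved the female minus male difference in genes above 0 between -908 and 518. That in the TPM percent of the 10 most abundant genes lay between 0.408 (without female tree 1) and 1.43 (without female tree 2), against 0.771 with all trees. That of the 100 most abundant genes lay between -0.794 and 1.39. With so few trees the exact permutation tests cannot give a p under 0.05, so none of these differences could have passed. Mean correlations over the 1000 most abundant genes were 0.909 within female, 0.957 within male and 0.779 between the sexes. As Spearman ranks they were 0.808, 0.828 and 0.679. Leaving out each library gave 0.872 to 0.899 within female and 0.886 to 0.916 within male trees. The cause of these shifts was not tested. Some of these settings used fewer genes, units or libraries. The test of fixed gene lists was not run, since no identifiers were paired with names. Unknown depth limits what a listed 0 shows.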

Other observations

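The tests of explanations, of direction by expression level, of directions within components and of other splits, the component sums and the removal of the genes private to female tree 2 were chosen after the results they bear on were seen. So was leaving out each library for the library measures and correlations. The scalings, the left-out libraries for calls and for genes of one sex, the replicate block, the filters, the pseudocounts, the array weights, the fit without the trend and the test against a 2-fold change were fixed before the data were examined. Called genes were found in every bin of expression level examined, with 10.1% called among genes averaging 5 to 10 TPM and 16.3% among those of 100 TPM or more. The direction changed with level: among genes averaging 100 TPM or more, 131 were higher in female and 84 higher in male trees (60.9% female), against 39.5% female among called genes below 100 TPM (Fisher's exact test, two-sided, p = 6.21e-10, across genes, which are not independent replicates). After TMM-type scaling these shares were 73.4% and 45.4%, and after quantile normalization 48.8% and 49.4% (Fisher's exact p = 0.889), so this pattern is not kept under that scaling. At 100 TPM or more the female and male counts were also closer in proportion without female tree 1 (76 and 73) or 3 (93 and 66), without male trees 1 (71 and 57), 2 (59 and 57) or 3 (65 and 54), with the replicate number as a block (76 and 70), without the trend (55 and 44), in component sums (120 and 95), without a filter (122 and 81), with pseudocounts of 0.1 (123 and 81) and 0.01 (111 and 76), and in the test against a 2-fold change (9 and 10). They were further apart in proportion without female tree 2 (123 and 76), with a filter of 5 TPM (137 and 83), with array weights (151 and 95) and without the genes private to female tree 2 (141 and 83).

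Called genes of one Trinity component mostly shared a direction. Of 678 components with 2 or more called genes, 474 had all of them higher in one sex and 204 had genes in both directions. Shuffling the directions over these 1679 genes 10000 times gave 383 mixed components on average and never fewer than 337 (permutation p = 1e-04, the smallest these shuffles can give). The shuffles treat the genes as independent, whereas genes of one component can be gene copies, sequence versions or fragments. A shared direction is therefore no evidence about the sexes.

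The 420 genes of female and 645 genes of male trees listed at 0 in the other sex may be sequence versions that differ between the sampled trees, or genes silent, missing or below detection in one sex. If the other genes of the component were the version of the opposite sex, they should move the other way. They did not: the summed TPM of the other genes had a median log2 difference of 0.43 (female minus male; 95% bootstrap interval over components 0.25 to 0.61) for the 290 female genes with such partners and -0.65 (-0.77 to -0.48) for the 445 male ones, against -0.12 over all 28228 such genes. The other genes were at least 2-fold higher in the opposite sex in 19 of the 290 (6.55%, against 10.3% of all such genes) and 14 of the 445 (3.15%, against 6.83%). They were at least 2-fold higher in the same sex in 33.1% and 36.2%, against 6.83% and 10.3%. The other genes were thus seldom 2-fold higher in the opposite sex. They can also be fragments of the same version or other genes of one sex, which would move with the gene. In 83.1% of the 290 and 84.3% of the 445 they reached 1 TPM in a library of the opposite sex. A split of versions between the sexes within a component is therefore not excluded. Versions assembled into separate components, sex itself, and a shared parentage of the trees of one sex, which the labels do not give, and the unknown depth behind each 0 stay open and were not tested.

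The 1215 genes of female tree 2 may come from RNA of another organism on or in that twig, from sequence versions of genes that the other trees also express, or from another organ or stage of the yew itself. Versions assembled within a component are argued against for the 435 genes that have another listed gene there: in 31 of them (7.13%) the component reached 1 TPM in another library, while 83.1% of the corresponding female-only genes and 84.3% of the male-only genes had partners at that level in a library of the opposite sex. The other 780 (64.2%, against 35.6% of all listed genes) are alone in their component, so versions assembled apart stay open for them. Another organism and another organ or stage cannot be told apart. Of the genes at 10 TPM or more in female tree 2, 1073 lay under 1% of that level in each other library (0 to 4 for the other libraries), 1007 of them listed at 0 there, and in 139 the highest other library lay at 1% to 20% (8 to 42 for the other libraries). A bound for another organ or stage, named after the counts were seen, asked for as many genes at 1% to 20% as under 1%. It was not reached, but the 139 also exceed what the other libraries show. Another organ or stage need not give equal numbers, so this bound decides nothing. Among the genes under 20% that are above 0 elsewhere, which are not among the 1215, 32.2% lay under 1%. No sequence or name was at hand to tell the species. Removing the 1215 genes and rescaling left 4822 calls, 4761 of them among the 4825.

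The excess of genes higher in male trees (59.6% of calls) may come from scaling each library to one total. Under TMM-type scaling the share was 53.5%, between the 52% below which it would point to scaling and the 57% above which it would exclude it. Under quantile normalization it was 50.6%, below 52%, but the bounds were named for TMM-type scaling, and quantile normalization gives all libraries the same distribution, so it would also remove a wider rise. The 2 scalings thus differ, and a scaling effect and a wider rise in male trees cannot be told apart without a reference of known amount. Each such scaling assumes that most genes do not differ. Multiplying a library by a factor does not change a 0. Of the genes listed at 0 in the other sex, 412 were called higher in female and 631 higher in male trees. The unknown depth behind each 0 limits what these counts show.

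The 6 libraries can be split into groups of 3 in 10 ways, which is too few for a share under 0.05. The split by sex was the 1 split with as many genes for all calls (4825), for calls of at least 2-fold (3925), and for calls higher in female (1951) or male trees (2874). The highest of the other 9 splits gave 0 genes in limma on each count. Each of those splits mixes the sexes, so the sex difference widens the spread within their groups and lowers their calls. Their 0 is therefore not the count expected by chance, and no conclusion is drawn from it. At an unadjusted p under 0.05 those splits gave 763 to 3448 genes and the split by sex 10346. limma was the one tool run on them.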
